A study of Mus musculus with 9 samples.

How the data were processed

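The counts per gene and the FPKM values of the 9 libraries were used as deposited by the authors. Per the submitters' processing notes, HISAT2 2.0.4 and StringTie 1.3.0 were used with the builds mm10 and GRCm38.p4, and the notes give no role or order of these tools. The program that made the gene counts and the strand setting are not given in the sources used here. The deposited FPKM values lay within 0.083% of the counts divided by length and library total over 150383 values. Per the labels, total RNA was taken from mouse livers and mRNA libraries were made from it.

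The count table held 34745 Ensembl genes, of which 14460 had 0 counts in every library. Of the gene IDs 34267 were found in GENCODE M21, and 27699 of these had the same coordinates. Genes with a symbol shared by other IDs were told apart by ID, and 67 symbols were shared. Tests used the genes kept by filterByExpr of edgeR (minimum count 10 in 3 libraries), which left 13701 genes that held at least 99.868% of the counts of each library.

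Analyses were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Libraries were scaled with TMM factors. All 9 libraries were fitted in a single negative binomial model with a mean for each group and no block, and contrasts were tested with the robust quasi-likelihood F-test of edgeR. The common dispersion was 0.0409, with 6 residual and 5.24 prior degrees of freedom. Genes with a Benjamini-Hochberg adjusted p below 0.05 in a comparison are said to have changed, risen or fallen. "Adjusted over the list alone" means that the same p-values were adjusted over the tested members of the list.

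A total of 36 gene lists were fixed before the values were seen, and 702 of their 703 genes were in the table. They are collagens and structural matrix, matrix cross-linking and remodelling, stellate cells and myofibroblasts, the TGF-beta pathway, sinusoidal endothelium, capillary-type and activated endothelium, Kupffer cells, recruited monocytes and macrophages, neutrophils, T and NK cells, B and plasma cells, cholangiocytes and ductular cells, inflammatory cytokines and chemokines, interferon-stimulated genes, the cell cycle, p53 targets, NRF2 targets, the unfolded protein and integrated stress response, xenobiotic phase I enzymes, pericentral and periportal hepatocyte genes, coagulation and fibrinolysis, heparan sulfate, chondroitin and hyaluronan metabolism, fatty acid oxidation, lipogenesis, cholesterol synthesis, bile acid synthesis and transport, the acute phase, fetal liver and injury, male-biased and female-biased genes, the circadian clock, red blood cells, mitochondrially encoded genes, pancreatic acinar cells, and mesothelial and adipose cells. The 34 lists with at least 5 tested members were tested with camera of limma on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes. Each was tested again with a correlation estimated from the data, and with the rank-based form of camera.

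Genes were named by a rule fixed before the data were examined. For each comparison these were the 8 largest rises and 8 largest falls with adjusted p below 0.05, at least 5 CPM in the higher group and libraries that did not overlap between groups. To them were added up to 4 members, by p, of each list that passed and of 7 lists described in every case, and 12 fixed genes. Genes named beyond the rule are said to have been chosen after their values were seen. These include, in the comparison of TAA with control, Col5a3, Mmp19, Ecm1, Skil, Gstp1, Ctnnbip1, Gldc, Aldh3a2, Rhbg and Axin2, and in that of sulodexide with vehicle, Sesn2, Cxcl14, Cx3cl1 and Ecm1. Where a group had 0 counts of a gene, a lower bound of the fold change was taken from 3 counts over the group. With 1 to 3 counts, the ratio of counts is given with a 95% interval.

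In a self-test, 50 genes for each fold were changed in simulated counts with the dispersion of the real libraries. For TAA against control 22%, 58%, 96% and 96% of the genes changed 1.5-fold, 2-fold, 4-fold and 8-fold were recovered, and 9.33% of the calls were false. For sulodexide against vehicle 14%, 62%, 94% and 98% were recovered and 5.63% of the calls were false. For sulodexide against control 12%, 62%, 94% and 98% were recovered and 5% of the calls were false. The changed list was found by camera with either correlation, and 0 of 19 unchanged lists passed. As simulated genes were drawn independently, this does not show how often camera passes an unchanged list whose genes vary together.

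Expected overlaps were taken from independent calls. The effect of shared libraries was simulated 50 times. Reads were not used here, and transcripts and splicing were not analysed here. Results for some list members named by the rule are not reported here.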

Results

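RNA sequencing was used to measure gene expression in the livers of C57BL/6 mice in 3 groups of 3 libraries each. Thioacetamide (TAA), a compound that hepatocytes activate to toxic products and that is used to induce liver fibrosis in rodents, was given in the drinking water at 400 mg/L for 16 weeks in a pair of the groups. During the last 4 weeks, from week 13 on, 1 of these groups received sulodexide each day and the other its vehicle, while TAA was continued. Sulodexide is a glycosaminoglycan drug made of a heparin fraction and dermatan sulfate. The remaining group served as control. The counts assigned to genes came to 14974495, 13803697 and 14928254 in the control libraries. They came to 15716249, 14386196 and 15959865 in the TAA with vehicle libraries and to 16316014, 16655951 and 15031275 in the TAA with sulodexide libraries. A total of 13701 of 34745 genes had enough counts to be tested. Within groups, the log2 expression values of pairs of libraries correlated across genes with Pearson's r from 0.968 to 0.98, where genes are not independent replicates. Between groups, r ranged from 0.877 to 0.921 for control against vehicle, from 0.937 to 0.947 for control against sulodexide and from 0.942 to 0.974 for vehicle against sulodexide. On the first principal component, which held 62.1% of the variance, the control libraries lay between -73.6 and -68.9, the sulodexide libraries between 11.2 and 17.9 and the vehicle libraries between 42.8 and 72.8. The labels speak of mice but do not state that each library came from a separate mouse, so p-values measure the spread between these samples. Levels are given in CPM, the counts of a gene relative to scaled library totals, as mean ± SD with n = 3 per group. Changes of genes are fitted log2 fold changes with a standard error (SE) and edgeR's adjusted p. Intervals and lower bounds given for genes with few counts cover counting error only.

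Livers after 16 weeks of TAA with vehicle were compared with control livers. The labels do not say if controls got vehicle, so TAA and vehicle are not told apart. Genes of the fibrous matrix, of bile duct cells, of white blood cells and of the p53 and NRF2 stress responses rose, and genes of hepatocyte function fell, though of the 24 lists that passed camera with the preset correlation 0 passed with an estimated one. Col1a1 (ENSMUSG00000001506, GRCm38 chromosome 11, 94936224 to 94953042), a chain of the main fibrillar collagen of scars, rose 30.1-fold, from 3.36 ± 0.915 to 102 ± 42.3 CPM (edgeR adjusted p = 7.18e-05). Phlda3 (ENSMUSG00000041801, chromosome 1, 135766119 to 135769136), a p53 target that restrains Akt signalling, rose 63.0-fold, from 0.584 ± 0.0683 to 37.4 ± 2.48 CPM (adjusted p = 1.9e-08). Slc1a2 (ENSMUSG00000005089, chromosome 2, 102658659 to 102790784), the glutamate transporter of the hepatocytes next to the central vein, fell by 8.14 on the log2 scale (SE 0.29), from 153 ± 25.1 to 0.526 ± 0.255 CPM (adjusted p = 4.49e-08). In all, 5953 of the 13701 genes changed, with 3161 higher and 2792 lower in TAA livers.

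Among collagens and structural matrix genes, 25 of 29 tested members rose and 1 fell, with the same counts when adjusted over the list alone (camera adjusted p = 1.46e-09). Col3a1 (ENSMUSG00000026043, chromosome 1, 45311538 to 45349706) rose 12.2-fold, from 14.2 ± 1.82 to 174 ± 35.3 CPM (edgeR adjusted p = 1.29e-06). Col1a2 rose 11.6-fold, the elastic fibre protein gene Emilin1 3.89-fold and Sparc, which encodes a collagen-binding protein, 3.57-fold, while Col5a3 fell by 0.87 on the log2 scale. Of the enzymes that cross-link and remodel matrix, 17 of 21 rose and 1, Mmp19, fell, also when adjusted over the list alone (camera adjusted p = 8.82e-07). Here the gelatinase gene Mmp2 rose by 4.58 on the log2 scale (SE 0.42), the tissue plasminogen activator gene Plat by 5.96 (SE 0.59), Adamts2 by 2.76 (SE 0.25) and the transglutaminase gene Tgm2 by 1.55 (SE 0.15). Timp1, an inhibitor of matrix metalloproteases, was 80.9 times higher by its counts, with a 95% counting interval from 14.2 to 3220 (edgeR adjusted p = 0.000675). It overlaps Syn1, so its counts are uncertain. Stellate cell and myofibroblast markers rose in 11 of 19 cases and fell in 1, or 12 and 1 when adjusted over the list alone (camera adjusted p = 0.000526). Acta2, the smooth muscle actin of myofibroblasts, rose 3.30-fold (edgeR adjusted p = 0.00053), Pdgfra 3.55-fold and Ngfr 2.47-fold. Ecm1 fell by 0.49 on the log2 scale, a call that was lost without vehicle library 1 (adjusted p = 0.0561), and 2 genes of the list fell without control library 3. In the TGF-beta pathway 18 of 26 members rose and 1, the inhibitor gene Skil, fell, with the same counts adjusted over the list alone (camera adjusted p = 8.32e-05). Tgfb1 rose from 9.15 ± 1.48 to 22.6 ± 5.03 CPM (edgeR adjusted p = 0.000523), Tgfb3, which overlaps Ttll5, by 3.68 on the log2 scale, Ltbp2 by 4.41, Tgfb2 by 3.06 and Tgfbi by 1.11. With an estimated correlation the call of each of these 4 lists was lost, at adjusted p = 0.191.

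Capillary-type endothelial genes rose. In the list of capillary-type and activated endothelium, 8 of 19 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.00154, and adjusted p = 0.242 with an estimated correlation). Cd34 (ENSMUSG00000016494, chromosome 1, 194938819 to 194961279), a surface protein of capillary but not of normal sinusoidal endothelium, rose 12.6-fold, from 1.31 ± 0.127 to 16.5 ± 5.45 CPM (edgeR adjusted p = 7.9e-06). The basement membrane genes Nid1 and Lamb1 rose by 2.83 and 1.69 and the adhesion molecule gene Icam1 by 1.67. Sinusoidal endothelial markers did not pass as a list (camera adjusted p = 0.282, and adjusted p = 0.753 with an estimated correlation): 1 of 22, the nitric oxide synthase gene Nos3, rose by 0.96 and 4 fell, or 1 and 2 when adjusted over the list alone. The count of 4 dropped to 1 without control library 1 and to 2 without control library 2, vehicle library 2 or vehicle library 3, and was 6 without vehicle library 1. With scaling by total counts 4 of these markers rose and 0 fell, and the list's median log2 change went from -0.28 to 0.12. Fcgr2b fell by 0.73, while the calls of Bmp2 and Kdr, which fell by 0.58 and 0.49, were lost without control library 1 (adjusted p = 0.0716 and 0.132). The call of Kdr was lost also without control library 2 (0.0515) and without vehicle library 1, 2 or 3 (0.055, 0.106 and 0.0629). The scavenger receptor gene Stab2 (log2 change -0.34, adjusted p = 0.205, and 0.05 with scaling by total counts or in FPKM) and the hyaluronan receptor gene Lyve1 (0.41, adjusted p = 0.355) did not pass.

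Marker genes of several white blood cell types rose. Of the markers of recruited monocytes and macrophages 16 of 19 rose, or 17 when adjusted over the list alone (camera adjusted p = 2.18e-06), with the lipid-associated macrophage gene Trem2 up by 4.32 on the log2 scale (SE 0.56), Cx3cr1, which overlaps several genes, by 3.91 and Cd9 by 1.69. Gpnmb was 390 times higher by its counts (interval 69.7 to 15400). Neutrophil markers rose in 7 of 8 cases (camera adjusted p = 0.00803), among them S100a9 by 3.24, S100a8 by 3.51 and Csf3r by 2.46, and Ngp was 86.6 times higher by its counts (interval 23.7 to 719), with 10.3, 1.29 and 1.57 CPM in vehicle libraries 1 to 3. Its fitted log2 change went from 6.17 to 4.54 without vehicle library 1. T and NK cell markers rose in 11 of 16 cases (camera adjusted p = 0.00154). Lck was up by 2.58, Cd8a by 3.46, Cd3e by 2.67 and Nkg7 by 3.42. With quantile normalization these counts were 4 for neutrophils and 5 for T and NK cells. B and plasma cell markers rose in 6 of 9 cases, or 8 when adjusted over the list alone (camera adjusted p = 0.000651). Jchain was up by 4.08, Cd22 by 1.80 and the antibody chain genes Igkc and Iglc1 by 4.07 and 4.18. Antibody chains share sequence with related segments, so their counts are uncertain. The neutrophil and T and NK counts were the same when adjusted over the lists alone. Vehicle library 1 stood above the other two: the mean log2 CPM relative to control was 3.972, 1.559 and 2.04 for neutrophil markers and 2.546, 0.776 and 1.535 for T and NK markers in vehicle libraries 1 to 3. Without it 5 neutrophil markers and 9 T and NK markers rose, and both lists passed (camera adjusted p = 0.00756 and 0.00464). With an estimated correlation, adjusted p = 0.191 for the monocyte list, 0.423 for neutrophils, 0.429 for T and NK cells and 0.191 for B cells. Inflammatory cytokines and chemokines rose in 9 of 17 cases and fell in 1, also over the list alone (camera adjusted p = 0.0294, and adjusted p = 0.443 with an estimated correlation). Cxcl14 was up by 2.71, Cx3cl1 by 4.04 and Cxcl16, which overlaps Zmynd15, by 1.3, while Il18 fell by 1.38, with 2 lower without vehicle library 1. That list did not pass without vehicle library 1 (adjusted p = 0.119) or with scaling by total counts (0.246), nor did the neutrophil list with that scaling (0.0945). Kupffer cell markers did not pass as a list (camera adjusted p = 0.755): 2 of 13 rose and 3 fell. Interferon-stimulated genes did not pass either (adjusted p = 0.42), with 2 of 21 higher and 5 lower, and passed without vehicle library 1 (0.0415). The number of interferon-stimulated genes that rose was 1 without control library 1, 2 or 3 or vehicle library 1 and 4 without vehicle library 2.

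All 15 tested cholangiocyte and ductular markers rose, also when adjusted over the list alone (camera adjusted p = 4.56e-07). The tight junction gene Cldn7 (ENSMUSG00000018569, chromosome 11, 69964779 to 69967885) rose 10.2-fold, from 0.705 ± 0.219 to 7.35 ± 2.68 CPM (edgeR adjusted p = 0.000172), and the epithelial transcription factor gene Ehf (ENSMUSG00000012350, chromosome 2, 103263433 to 103303278) 12.3-fold. Krt23 rose 7.58-fold, and Cldn4 was 103 times higher by its counts (interval 35.2 to 504). Genes of the fetal or injured liver rose in 13 of 16 cases and fell in 1, also over the list alone (camera adjusted p = 9.53e-08), including Afp, the fetal serum albumin-like protein, from 1.11 ± 0.213 to 40.6 ± 1.66 CPM (edgeR adjusted p = 8.62e-06). The oncofetal proteoglycan gene Gpc3 rose by 7.53 on the log2 scale (SE 0.25), Anxa2 by 3.26 (SE 0.25) and Anxa5 by 2.09 (SE 0.15); the 1 gene that fell, Ctnnbip1, lost its call without control library 1 (0.0836), control library 2 (0.0567) or vehicle library 2 (0.0983). In the cell cycle list 22 of 27 members rose and 0 fell, also over the list alone (camera adjusted p = 9.66e-08): Ccnd1, which encodes cyclin D1, rose from 31.0 ± 3.3 to 131 ± 32.7 CPM (edgeR adjusted p = 0.000164), Kif20a by 3.10 on the log2 scale, Cdc20 by 3.99 and Mcm6 by 1.53, of which Ccnd1, Kif20a and Cdc20 overlap other genes. Of the p53 targets 15 of 17 rose, also over the list alone (camera adjusted p = 1.9e-08). Sesn2 was up by 2.46 (SE 0.14), Ccng1 by 2.21 (SE 0.14) and Eda2r by 5.03 (SE 0.33). NRF2 targets, which detoxify electrophiles and oxidants, rose in 18 of 21 cases and fell in 1, Gstp1, also over the list alone (camera adjusted p = 4.02e-10). The carbonyl reductase gene Cbr3 rose by 7.06 (SE 0.35), the export pump gene Abcc4 by 5.33 (SE 0.29), and the glutathione transferase genes Gsta2 and Gstm3, which have close paralogs, by 4.47 (SE 0.18) and 4.30 (SE 0.21). Each of these 5 lists lost its call with an estimated correlation, at adjusted p = 0.191.

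Hepatocyte genes of both ends of the lobule fell. Pericentral genes, expressed near the central vein where TAA is activated, fell in 10 of 20 cases and rose in 3, also over the list alone (camera adjusted p = 0.00206): the ornithine aminotransferase gene Oat fell by 5.39 on the log2 scale (SE 0.28), from 882 ± 70.9 to 21 ± 3.96 CPM, while Aldh3a2, Rhbg and Axin2 rose. Periportal genes fell in 12 of 18 cases, also over the list alone (camera adjusted p = 0.000281), with the urea cycle genes Otc and Asl down at log2 changes of -1.98 and -1.43, the antibody transporter gene Pigr at -1.99 and the gluconeogenesis gene Pck1 at -1.39; 1 member, Gldc, rose, a call lost without control library 3 (adjusted p = 0.0527). Coagulation and fibrinolysis genes of the liver fell in 18 of 21 cases, or 19 over the list alone, and none rose (camera adjusted p = 2.97e-08). Klkb1, which overlaps Cyp4v3, lay at a log2 change of -2.25, F9 at -1.40, F7 at -1.36, F11 at -1.16, the heparin cofactor gene Serpind1 at -0.87 and the antithrombin gene Serpinc1 at -0.61. With quantile normalization 6 periportal genes and 11 coagulation genes fell. Bile acid synthesis and transport genes fell in 14 of 19 cases and rose in 3, also over the list alone (camera adjusted p = 0.00106), with the uptake carrier genes Slc10a1 and Slco1b2 at -1.93 and -1.51 and the conjugating enzyme gene Baat at -1.33. Phase I enzymes of xenobiotic metabolism fell in 11 of 24 cases and rose in 5, also over the list alone (camera adjusted p = 0.0175): Cyp2c37 lay at a log2 change of -3.75, Cyp2c54 at -2.21 and Cyp2c50 at -1.81, while Cyp2a5 rose by 2.44, and these families have close paralogs. The median log2 change of the phase I list was -0.33, and 0.07 with scaling by total counts. Male-biased liver genes fell in 13 of 16 cases, or 14 over the list alone (camera adjusted p = 1.53e-06). Serpina12 lay at a log2 change of -4.09, C8b at -2.45, Ugt2b1 at -1.89 and Mup3 at -1.78. Female-biased genes rose in 6 of 9 cases, with 1 lower when adjusted over the list alone (camera adjusted p = 0.0181, and 0.16 with scaling by total counts), including Cyp3a44 by 6.44, Prom1 by 3.22 and Cyp2b9 by 2.68. The labels do not give the sex of the mice, so a difference in sex between the groups stays open for these and the Mup genes. Mitochondrially encoded genes fell in 12 of 13 cases, also over the list alone (camera adjusted p = 9.53e-08). mt-Nd2 lay at a log2 change of -1.70, mt-Nd4l at -1.65, mt-Cytb at -1.49 and mt-Co2 at -1.47; their share of all counts was 10.5% ± 0.522 in control, 5.76% ± 0.886 in vehicle and 6.83% ± 0.891 in sulodexide libraries. The estimated correlation gave an adjusted p of 0.295 for the male-biased list, 0.337 for the female-biased list and 0.191 for each of the other 6 lists.

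Cholesterol synthesis genes rose in 11 of 21 cases and fell in 2, or 12 and 3 over the list alone (camera adjusted p = 0.0237, and adjusted p = 0.641 with an estimated correlation). Hmgcs1 rose by 1.79, Sqle by 1.40, Fdft1, which overlaps Ctsb, by 1.15 and Dhcr7 by 0.87. The list did not pass without control library 3 (0.0549), without vehicle library 2 (0.11) or with scaling by total counts (0.0657), and 7 of its genes rose without control library 2, control library 3 or vehicle library 2 and 1 fell without control library 2, vehicle library 1 or vehicle library 3. Genes that handle heparan sulfate, chondroitin and hyaluronan went both ways, with 10 of 29 higher and 8 lower, or 13 and 8 over the list alone (camera adjusted p = 0.573, and adjusted p = 0.798 with an estimated correlation). The heparanase gene Hpse rose by 1.03 (edgeR adjusted p = 0.007) and the sulfatase gene Sulf2, which overlaps Ncoa3, by 0.94, whereas the syndecan gene Sdc2 lay at a log2 change of -1.11 and the hyaluronidase gene Hyal1, which overlaps Nat6, at -1.72. The number that fell was 5 without vehicle library 2. Fatty acid oxidation genes (3 of 24 higher, 9 lower, camera adjusted p = 0.144), lipogenesis genes (7 of 20 higher, 4 lower, 0.42), genes of the unfolded protein response (3 of 16 higher, 4 lower, 0.287) and acute-phase genes (4 of 21 higher, 5 lower, 0.292) did not pass as lists. The fatty acid oxidation list had a median log2 change of -0.31, a mean of 0.09 and a test direction of lower, and passed without control library 3 (0.0315); its median was 0.08 with scaling by total counts. The number of acute-phase genes that rose was 2 without control library 1 or 2 or vehicle library 1 or 3. Circadian clock genes, with 4 of 17 higher and 10 lower (0.0641), passed without control library 3 (0.0377), with scaling by total counts (0.00969) and with rank-based camera (0.0453), and red blood cell markers, with 1 of 5 lower (0.836), did not pass, with 2 higher without control library 2. Pancreatic acinar markers (1 tested, Cela1, which fell by 1.51) and mesothelial and adipose markers (3 tested, of which Wt1 rose) had too few tested members for a set test.

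The largest rises by the rule for named genes included Gipc2, with 0 counts in control livers and 10.9 ± 2.98 CPM with TAA, which was at least 139-fold higher. Tinag and the cystine transporter gene Slc7a11 were likewise at least 85.2-fold and 71.2-fold higher than a control level of 0 counts. Cyp2a4 rose from 1.86 ± 2.35 to 1620 ± 154 CPM (edgeR adjusted p = 4.25e-05) and is nearly identical to Cyp2a5. The matrix metalloprotease gene Mmp7 rose by 7.60 on the log2 scale (SE 1.06), and Scube3 was 225 times higher by its counts (interval 40.0 to 8900). The largest falls were mostly of major urinary proteins, whose near-identical copies make their single values uncertain: Mup15 lay at a log2 change of -11.04, Mup11 at -9.75, Mup17 at -9.65 and Mup16 at -6.52, and Mup10 was 171 times lower by its counts (interval 46.9 to 1420). Serpina4-ps1 fell by 6.84. Moxd1 was 420 times lower by its counts (interval 143 to 2040), but its adjusted p of 0.0461 rose to between 0.0701 and 0.177 without any 1 of the 6 libraries. Of the 118 called genes named by rule here, 115 kept their call with every library left out in turn.

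The balance of rises and falls against control differed between scalings. Of the changed genes 53.1% rose, and 54% with DESeq2 size factors and 48.3% with quantile normalization, but 83.3% with scaling by total counts. In a limma fit to the deposited FPKM values, where both the test and the scaling differ, 82.9% rose. Scaling by total counts moved the median log2 change of all genes by 0.40 for vehicle against control, by 0.26 for sulodexide against control and by -0.14 for sulodexide against vehicle, and the limma fit by 0.21 and 0.12 for the first pair of these.

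**Figure D1:**
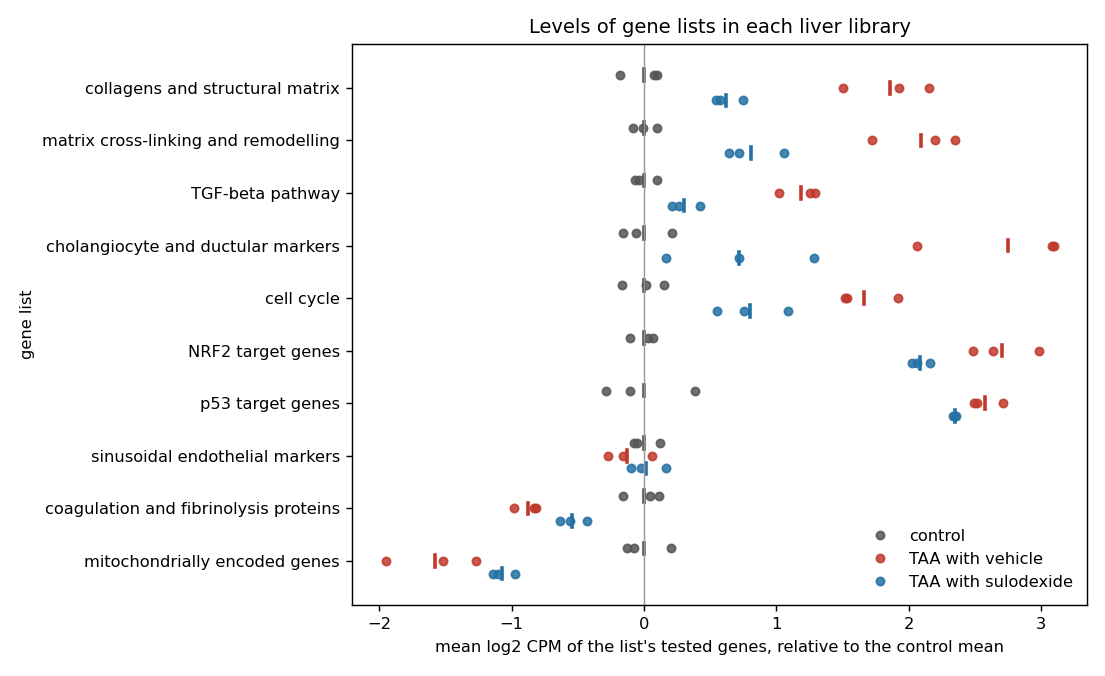
Mean log2 CPM of the tested genes of 10 lists (vertical axis) in each of the 9 libraries, relative to the mean of the control libraries (horizontal axis, log2), with 1 point per library and a tick at each group mean. Collagens lay at 1.86 ± 0.33 with vehicle and 0.62 ± 0.11 with sulodexide (SD), and p53 targets at 2.58 ± 0.12 and 2.35 ± 0.01.

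Livers of mice given TAA and sulodexide were compared with those given TAA and vehicle. With sulodexide, genes of the matrix, of ductular cells and of TGF-beta signalling were lower, and some hepatocyte genes, 3 of 21 for coagulation and 5 of 21 for the acute phase, were higher. With an estimated correlation 0 lists passed camera, and with 1 library left out the lowest counts of these rises were 1 and 2. Col1a1 fell 8.18-fold, from 102 ± 42.3 to 12.4 ± 5.51 CPM (edgeR adjusted p = 0.0087), and Col3a1 4.47-fold, from 174 ± 35.3 to 39.0 ± 7.96 CPM (adjusted p = 0.00251). Cd34 fell 4.26-fold, from 16.5 ± 5.45 to 3.87 ± 0.424 CPM (adjusted p = 0.00532). Cd163 (ENSMUSG00000008845, chromosome 6, 124304656 to 124330527), a scavenger receptor of resident macrophages, rose 5.50-fold, from 4.89 ± 1.92 to 26.8 ± 8.88 CPM (adjusted p = 0.00913), where control livers had 18.9 ± 7.13 CPM. Of 13701 genes 658 changed, with 191 higher and 467 lower. Single libraries moved this count: it was 177 without vehicle library 1, 143 without vehicle library 3, 140 without sulodexide library 2 and 362 without sulodexide library 3. Of the changed genes 29% rose, against 27.2% with DESeq2 size factors, 35.6% with quantile normalization, 11.6% with scaling by total counts and 9.38% in the limma fit to FPKM.

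Of the collagens and structural matrix genes 17 of 29 fell and 0 rose, or 22 fell when adjusted over the list alone (camera adjusted p = 6.5e-17). Col1a2 lay at a log2 change of -2.34 (SE 0.26), Emilin1 at -1.25 (SE 0.16), Sparc at -1.34 (SE 0.19) and the elastin gene Eln at -3.14 (SE 0.41). Matrix cross-linking and remodelling genes fell in 9 of 21 cases, or 15 over the list alone (camera adjusted p = 1.83e-10), with the lysyl oxidase gene Loxl1 at -2.94 (SE 0.36), Mmp2 at -2.92 (SE 0.37), Plat at -3.24 (SE 0.44) and Adamts2 at -1.83 (SE 0.23). The number was 5 without vehicle library 1, 4 without vehicle library 3 and 5 without sulodexide library 2. Timp1 did not pass (log2 change -2.23, edgeR adjusted p = 0.0592). TGF-beta pathway genes fell in 9 of 26 cases, or 15 over the list alone (camera adjusted p = 4.12e-08), and in 3 without vehicle library 3 or sulodexide library 2. Tgfb3 fell 6.21-fold, to 2.21 ± 0.287 CPM (edgeR adjusted p = 0.00302), and the latent binding protein gene Ltbp2 by 3.13 on the log2 scale (SE 0.43). The call of Tgfb2, at a log2 change of -2.03, was lost without vehicle library 3 (adjusted p = 0.066). Tgfb1 did not pass (log2 change -0.59, adjusted p = 0.117). Stellate cell and myofibroblast markers fell in 5 of 19 cases and rose in 1, or 9 and 1 over the list alone (camera adjusted p = 3.26e-05). The number that fell was 2 without vehicle library 1 and 1 without vehicle library 3, sulodexide library 2 or sulodexide library 3. Cygb, Ngfr and Pdgfrb, at log2 changes of -1.54, -0.83 and -1.26, lost their calls without vehicle library 1 (adjusted p = 0.0705, 0.0708 and 0.0802), vehicle library 3 (0.0642, 0.0786 and 0.0768), sulodexide library 2 (0.0803, 0.0775 and 0.0775) or sulodexide library 3 (0.0611, 0.0611 and 0.0716), and Pdgfrb also without sulodexide library 1 (0.0669). The 1 that rose, Ecm1, lost its call without any 1 of the 6 libraries (0.0528 to 0.171), and Acta2 did not pass (log2 change -0.92, adjusted p = 0.0652). With an estimated correlation, adjusted p = 0.134 for the collagen and remodelling lists, 0.0694 for TGF-beta and 0.219 for stellate cells.

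Ductular markers fell in 11 of 15 cases, or 14 over the list alone (camera adjusted p = 2.2e-12, and adjusted p = 0.151 with an estimated correlation). Cldn7 fell 5.86-fold, from 7.35 ± 2.68 to 1.26 ± 0.576 CPM, and Ehf 6.43-fold, from 10.1 ± 4.32 to 1.57 ± 0.571 CPM (edgeR adjusted p = 0.00913 for each). The count of 11 was 5 without vehicle library 1 or sulodexide library 2 and 3 without vehicle library 3 or sulodexide library 3. Cldn4 lay at a log2 change of -3.33 (adjusted p = 0.0514 without sulodexide library 3) and the cystic kidney disease gene Pkhd1 at -1.51 (0.0502 without vehicle library 3). Genes of the fetal or injured liver fell in 6 of 16 cases, or 11 over the list alone (camera adjusted p = 8.52e-08, and adjusted p = 0.134 with an estimated correlation), and in 3 without vehicle library 1, vehicle library 3 or sulodexide library 2. S100a11 lay at a log2 change of -1.45, Anxa2 at -1.40 and Anxa3 at -1.41, while the call of Anxa5, at -0.77, was lost without vehicle library 1 (0.0685), vehicle library 3 (0.0642) or sulodexide library 2 (0.0719). In the cell cycle list 6 of 27 fell, or 17 over the list alone (camera adjusted p = 4.06e-09, and adjusted p = 0.151 with an estimated correlation). Mcm6, Cdc20, Mki67 and Cdk1 had log2 changes of -1.01, -1.70, -1.38 and -1.16 and lost their calls without vehicle library 1 (0.0677, 0.0958, 0.121 and 0.112) or vehicle library 3 (0.0642, 0.0568, 0.0719 and 0.0907). The number of cell cycle genes that fell was 0 without vehicle library 1 or 3, 1 without sulodexide library 1 or 3 and 3 without sulodexide library 2. The call of Mcm6 was lost also without sulodexide library 2 (0.0599). Those of Cdc20, Mki67 and Cdk1 were lost without sulodexide library 1 (0.0544, 0.0794 and 0.0734) or 3 (0.0797, 0.0902 and 0.0688), and that of Cdk1 without sulodexide library 2 (0.0596).

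NRF2 targets fell in 4 of 21 cases, or 9 over the list alone (camera adjusted p = 2.97e-06, and adjusted p = 0.134 with an estimated correlation): Osgin1 by 2.22, Cbr3 by 1.31, Abcc4 by 1.23 and Gsta2 by 0.64 on the log2 scale. The number was 2 without vehicle library 1, 8 without vehicle library 2 and 1 without sulodexide library 2 or 3, and 7 with scaling by total counts. The calls of Osgin1 and Cbr3 were lost without sulodexide library 3 (adjusted p = 0.0542 and 0.0618), those of Cbr3 and Abcc4 without sulodexide library 2 (0.0638 and 0.0681), and that of Abcc4 without vehicle library 1 (0.0625). Gsta2 lost its call without any 1 library but vehicle library 2 (0.0633 to 0.169). p53 targets did not pass as a list (camera adjusted p = 0.315), and 1 of 17, Sesn2, fell, by 0.54, a call lost without any 1 of the 6 libraries (0.0503 to 0.121). Cholesterol synthesis genes fell in 2 of 21 cases, or 6 over the list alone (camera adjusted p = 1.43e-05, and adjusted p = 0.368 with an estimated correlation), and in 4 with scaling by total counts or quantile normalization. The mevalonate pathway gene Mvd lay at a log2 change of -1.0 and the sterol sensor gene Insig1 at -0.73. Neither fell without sulodexide library 2 (0.0609 and 0.0765) or 3 (0.052 and 0.0633), Insig1 not without vehicle library 1 (0.0685), and 4 genes of the list fell without sulodexide library 1.

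Among endothelial genes, the capillary-type list was lower (camera adjusted p = 0.00628, and adjusted p = 0.368 with an estimated correlation) with 3 of 19 members lower, or 6 over the list alone. Lamb1 and Nid1, at log2 changes of -1.11 and -1.07, lost their calls without vehicle library 1 (adjusted p = 0.0673 and 0.157), vehicle library 3 (0.085 and 0.102), sulodexide library 2 (0.0554 and 0.149) or sulodexide library 3 (0.0643 and 0.107), which left Cd34 as the only one of 3, and Lamb1 also without sulodexide library 1 (0.0556). None of the 22 sinusoidal markers passed in edgeR, over all genes or over the list alone (camera adjusted p = 0.0852, and adjusted p = 0.618 with an estimated correlation). The list passed as higher without vehicle library 1 (0.00689) or sulodexide library 3 (0.0348) and with rank-based camera (0.0498). Mrc1, Oit3 and Clec4g had log2 changes of 0.70, 0.42 and 0.38, Stab2 of 0.31, Lyve1 of 0.51 and Nos3 of -0.44, and none passed. Kupffer cell markers were higher as a list (camera adjusted p = 0.00558, and adjusted p = 0.395 with an estimated correlation) but not without sulodexide library 2 (0.0719), with Cd163 the 1 of 13 that rose, also over the list alone, or 1 of 2 without sulodexide library 1. Monocyte and macrophage markers were lower (camera adjusted p = 0.00111, and adjusted p = 0.368 with an estimated correlation), with 2 of 19 lower, Cd9 at -0.94 and Cx3cr1 at -1.94, or 3 over the list alone. The number was 5 without vehicle library 2, 0 without vehicle library 1, sulodexide library 2 or sulodexide library 3 and 1 without vehicle library 3 or sulodexide library 1. Both calls were lost without vehicle library 1 (0.0938 and 0.0996), vehicle library 3 (0.085 and 0.0717), sulodexide library 2 (0.0969 and 0.0981) or sulodexide library 3 (0.0689 and 0.0542), and that of Cx3cr1 without sulodexide library 1 (0.0647). B and plasma cell markers were lower as a list with 0 of 9 members passing, also over the list alone (camera adjusted p = 0.0199, and adjusted p = 0.368 with an estimated correlation), but not without vehicle library 1 (0.187) or sulodexide library 1 (0.156) or with scaling by total counts (0.0721). Neutrophil, T and NK cell, inflammatory and interferon-stimulated genes did not pass as lists (camera adjusted p = 0.0879, 0.202, 0.465 and 0.11). Among them 2 of 17 inflammatory genes fell in edgeR, Cxcl14 and Cx3cl1, also over the list alone, and both calls were lost without vehicle library 3 (0.0978 and 0.0502), sulodexide library 2 (0.113 and 0.0636) or sulodexide library 3 (0.0591 and 0.0542), and that of Cxcl14 without vehicle library 1 (0.113) or sulodexide library 1 (0.0877). The neutrophil list passed as lower without vehicle library 2 (0.0131), vehicle library 3 (0.0331) or sulodexide library 2 (0.0198), the T and NK list without vehicle library 2 (0.00253) and the interferon list without vehicle library 2 (0.0316), vehicle library 3 (0.0209) or sulodexide library 2 (0.0433) and with rank-based camera (0.0498).

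Some hepatocyte genes were higher with sulodexide. Acute-phase genes rose in 5 of 21 cases, or 9 over the list alone with 1 lower (camera adjusted p = 3.8e-06, and adjusted p = 0.276 with an estimated correlation). Saa4 rose 2.86-fold, from 119 ± 12.6 to 341 ± 122 CPM (edgeR adjusted p = 0.00913), and Crp by 0.74 on the log2 scale (adjusted p = 0.0502 without vehicle library 3). Saa1 rose from 52.6 ± 12.9 to 397 ± 113 CPM and Saa2 from 29.2 ± 12.2 to 262 ± 77.4 CPM, as close paralogs that may share reads, and Serpina3n by 1.08 on the log2 scale. Their calls were lost without vehicle library 1 (0.0747, 0.0829 and 0.0713) or sulodexide library 2 (0.0715, 0.0896 and 0.0674). Those of Saa1 and Saa2 were lost also without vehicle library 3 (0.0786 and 0.1) or sulodexide library 3 (0.0633 and 0.0638), and that of Saa2 without vehicle library 2 (0.0562) or sulodexide library 1 (0.0612). The number of acute-phase genes that rose was 2 without vehicle library 1, vehicle library 3 or sulodexide library 2. Coagulation genes rose in 3 of 21 cases, or 9 over the list alone (camera adjusted p = 1.86e-06, and adjusted p = 0.297 with an estimated correlation). F9 rose 1.59-fold, from 88.7 ± 2.78 to 141 ± 11 CPM (edgeR adjusted p = 0.00913), and was called with every library left out in turn. F13b and Klkb1, at log2 changes of 0.62 and 0.57, lost their calls without vehicle library 1 (0.0751 and 0.129), vehicle library 3 (0.0513 and 0.132) or sulodexide library 2 (0.0719 and 0.132), which left 1 gene of the list, and Klkb1 also without sulodexide library 3 (0.0793). Serpinc1 (log2 change 0.25, adjusted p = 0.395) and Serpind1 (0.17, adjusted p = 0.516) did not pass.

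Bile acid synthesis and transport genes rose in 3 of 19 cases and fell in 1, or 5 and 1 over the list alone (camera adjusted p = 0.00374, and adjusted p = 0.276 with an estimated correlation). Cyp7a1 (ENSMUSG00000028240, chromosome 4, 6265612 to 6275633), the rate-limiting enzyme of bile acid synthesis, rose 4.06-fold, from 14.9 ± 5.93 to 60.4 ± 23.8 CPM (edgeR adjusted p = 0.0156). Its call, and those of Slco1b2 and Slc10a1 at log2 changes of 0.63 and 0.56, were lost without vehicle library 1 (0.0637, 0.0793 and 0.102) or vehicle library 3 (0.0656, 0.0706 and 0.0788), where 0 genes of the list rose. The 1 fall was lost without vehicle library 1 or sulodexide library 2. Without sulodexide library 2 the count was 1, as Slco1b2 (0.0674) and Slc10a1 (0.0559) lost their calls, and Slc10a1 also did without sulodexide library 1 (0.0701). Phase I enzymes rose in 4 of 24 cases and fell in 1, also over the list alone (camera adjusted p = 0.0277, and adjusted p = 0.276 with an estimated correlation), and did not pass as a list without sulodexide library 1 (0.0893) or 3 (0.0571). Cyp1a1, a target of the aryl hydrocarbon receptor, fell 6.83-fold, from 44.5 ± 20.4 to 6.51 ± 0.0539 CPM (edgeR adjusted p = 0.00595). Pericentral genes rose in 4 of 20 cases, also over the list alone (camera adjusted p = 0.0159, and adjusted p = 0.275 with an estimated correlation), and not as a list without sulodexide library 3 (0.0571). Oat, Cyp2c50, Cyp2c37 and Rgn had log2 changes of 1.22, 0.68, 0.81 and 0.75. None of these 4 was called without vehicle library 1 (0.065, 0.106, 0.157 and 0.16), vehicle library 3 (0.0684, 0.0794, 0.085 and 0.116) or sulodexide library 3 (0.0646, 0.0874, 0.0936 and 0.0918). Without vehicle library 2, 1 of them rose and the adjusted p was 0.0847 for Cyp2c50, 0.0626 for Cyp2c37 and 0.0519 for Rgn. Without sulodexide library 2, 2 of them rose and it was 0.102 for Cyp2c50 and 0.0883 for Rgn, and without sulodexide library 1 it was 0.0885 for Cyp2c37. With scaling by total counts 2 phase I genes and 2 pericentral genes rose, and with quantile normalization 2 pericentral genes. The number of phase I genes that rose was 0 without vehicle library 1 or 3, 1 without vehicle library 2 or sulodexide library 3 and 2 without sulodexide library 1 or 2. Among them Cyp2c54, at 0.94, was lost without vehicle library 1 (0.0703) or 3 (0.0555) and Cyp3a13, at 0.55, without any 1 library (0.0596 to 0.135).

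Periportal genes were higher as a list (camera adjusted p = 0.0149, and adjusted p = 0.368 with an estimated correlation), with Otc higher by 0.62 and G6pc lower by 0.89 among 18 members, or 2 higher and 1 lower over the list alone. The call of Otc was lost without vehicle library 1 (adjusted p = 0.132), vehicle library 3 (0.131), sulodexide library 2 (0.119) or sulodexide library 3 (0.0844), and that of G6pc without any 1 library but vehicle library 1 (0.0727 to 0.137). Male-biased genes were higher as a list (camera adjusted p = 3.8e-06, and adjusted p = 0.368 with an estimated correlation) with 1 of 16 higher, C8b by 0.98, or 6 over the list alone. C8b was not called without any 1 library but vehicle library 2 (0.0526 to 0.145), and the number of male-biased genes that rose was 0 without vehicle library 1, vehicle library 3, sulodexide library 2 or sulodexide library 3, 2 without vehicle library 2 and 3 without sulodexide library 1. Circadian clock genes rose in 7 of 17 cases, or 8 over the list alone (camera adjusted p = 1.27e-05, and adjusted p = 0.0694 with an estimated correlation). Nr1d1, a repressor within the clock that overlaps Thra, rose 1.65-fold (edgeR adjusted p = 0.0087), Dbp, which overlaps Sphk2, by 1.63 on the log2 scale (0.0509 without vehicle library 3), Bhlhe41 by 1.71 (0.0536 without sulodexide library 2) and Tef by 0.75 (0.0729 without vehicle library 1, 0.0508 without vehicle library 3 and 0.0675 without sulodexide library 2). The number of clock genes that rose was 3 without vehicle library 1 and 2 without vehicle library 3 or sulodexide library 2. Mitochondrially encoded genes were higher as a list (camera adjusted p = 2.01e-05, and adjusted p = 0.276 with an estimated correlation), with mt-Cytb the 1 of 13 that rose, by 0.68, or 1 of 2 over the list alone, a call that held only without sulodexide library 1 (0.0874 to 0.11 without each of the others). In the heparan sulfate list Hyal1 rose by 1.12 while Gpc3 and the basement membrane proteoglycan gene Agrn fell by 0.75 and 1.01, the only calls among 29, also over the list alone (camera adjusted p = 0.315, and adjusted p = 0.703 with an estimated correlation). Without vehicle library 3 none of the 3 was called (0.0656, 0.0706 and 0.0509). Hyal1 and Gpc3 were not called without vehicle library 1 (0.0829 and 0.0752) or sulodexide library 2 (0.083 and 0.0874), nor Gpc3 without sulodexide library 3 (0.052), where 2 genes of the list rose. Hpse did not pass (log2 change -0.33, adjusted p = 0.489). The lists of fatty acid oxidation (0 of 24 genes changed), lipogenesis (1 of 20 lower), the unfolded protein response (1 of 16 higher), female-biased genes (0 of 9) and red blood cells (0 of 5) did not pass (camera adjusted p = 0.22, 0.745, 0.569, 0.761 and 0.745). Without vehicle library 2, 1 fatty acid oxidation gene rose and 1 female-biased gene fell, without sulodexide library 1, 1 gene of each list fell, and the lipogenesis call was lost without vehicle library 1 or 3 or sulodexide library 2 or 3. The fatty acid oxidation list passed as higher without vehicle library 2 (0.0316) or sulodexide library 2 (0.0288), and the lipogenesis list, with a median of 0.05 (and -0.08 with scaling by total counts), a mean of -0.03 and a test direction of lower, passed without sulodexide library 1 (0.0466).

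Other genes among the largest rises were Eif4ebp3, from 8.39 ± 2.22 to 51.6 ± 26.1 CPM (edgeR adjusted p = 0.0087), which overlaps Ankhd1, and the complement gene C4a, from 14.2 ± 4.76 to 71.2 ± 17.7 CPM (adjusted p = 0.0082), a near-identical copy of C4b. Mcm10 rose from 13.1 ± 4.33 to 59.1 ± 17.1 CPM (adjusted p = 0.00532) and the zinc finger gene Zkscan7 by 1.88 on the log2 scale (adjusted p = 0.0101). The largest fall was that of Gabrp (ENSMUSG00000020159, chromosome 11, 33550781 to 33578959), a subunit of the GABA-A receptor, from 6.26 ± 1.89 to 0.463 ± 0.215 CPM (adjusted p = 0.00532). Fhl2 lay at a log2 change of -3.36, Tmem45a at -3.26, Scube3 at -3.25 and Crispld2 at -3.45, the latter with an adjusted p of 0.0596 without sulodexide library 2. In all, 32 of the 80 called genes named by rule in this comparison kept their call with every library left out in turn.

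**Figure D2:**
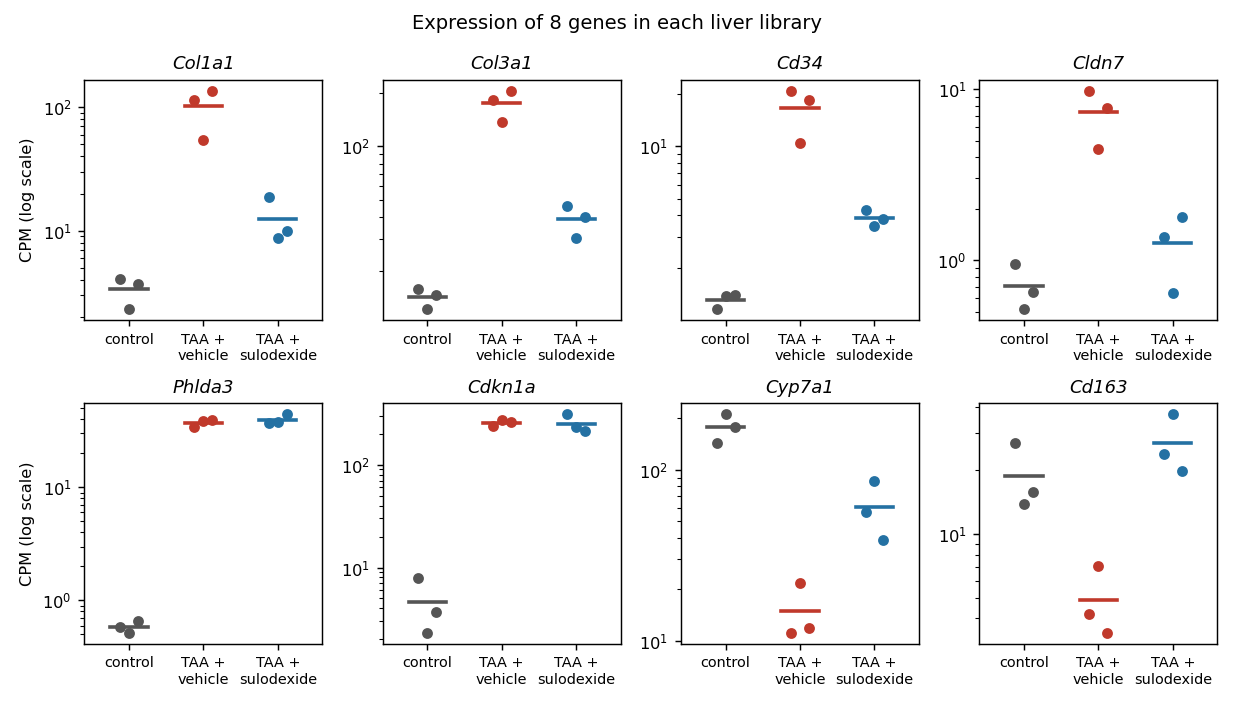
Expression of 8 genes in each of the 9 libraries in CPM (vertical axis, log scale), by group, with 1 point per library and a bar at the mean of each group. Col1a1, Col3a1, Cd34 and Cldn7 were lower with sulodexide than with vehicle, Cd163 and Cyp7a1 were higher, while Phlda3 lay at 37.4 and 39.6 CPM and Cdkn1a at 257 and 251 CPM with vehicle and with sulodexide.

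Livers of mice given TAA and sulodexide were also compared with control livers, which may not have had vehicle. Of 13701 genes 3101 changed, with 1537 higher and 1564 lower. Col1a1 was 3.68-fold and Col3a1 2.74-fold above control, at 12.4 ± 5.51 and 39.0 ± 7.96 CPM (edgeR adjusted p = 0.0161 and 0.00055). The call of Col1a1 was lost without control library 2 (0.0582). Cd34 was 2.95-fold above control (adjusted p = 0.00405). Phlda3 rose 66.9-fold, from 0.584 ± 0.0683 to 39.6 ± 4.07 CPM (adjusted p = 1.63e-08), and Cdkn1a, the cell cycle inhibitor induced by p53, 53.5-fold, from 4.62 ± 2.88 to 251 ± 50.2 CPM (adjusted p = 1.74e-05). Slc1a2 was at 0.572 ± 0.196 against 153 ± 25.1 CPM (adjusted p = 6.3e-08). Of the 108 called genes named by rule in this comparison, 81 kept their call with every library left out in turn. The count of changed genes was 2033 without control library 2 and 2064 without control library 3, and 49.6% of the changed genes rose, against 49.1% with DESeq2 size factors, 50.3% with quantile normalization, 81.4% with scaling by total counts and 77.9% in the limma fit to FPKM.

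Some matrix genes were above control. Collagens and structural matrix genes rose in 9 of 29 cases and fell in 1, or 14 and 1 over the list alone (camera adjusted p = 0.000215). Col1a2 was up by 1.19 on the log2 scale and Col5a3 down by 1.11. The number that rose was 5 without control library 1 or sulodexide library 1 and 3 without control library 2, and 19 with scaling by total counts. Remodelling genes rose in 8 of 21 cases and fell in 1, or 9 and 1 over the list alone (camera adjusted p = 0.00431). Mmp12 was up by 3.16 and Tgm2 by 0.76, while Mmp19 fell by 0.98. The number that rose was 4 without control library 2 or 3 and 5 without sulodexide library 1. Stellate cell markers rose in 3 of 19 cases and fell in 1, also over the list alone (camera adjusted p = 0.0169). Tpm2 lay at a log2 change of -1.60, and 1 gene rose without control library 1, control library 3 or sulodexide library 2, and 9 with scaling by total counts. TGF-beta pathway genes rose in 6 of 26 cases, also over the list alone, and did not pass as a list (camera adjusted p = 0.0633), but passed without control library 1 (0.0351). The number that rose was 2 without control library 1 and 3 without control library 2, and the call of Tgfb1, at a log2 change of 0.71, was lost without control library 1 (0.108), control library 3 (0.0783), sulodexide library 1 (0.0799) or sulodexide library 2 (0.087). Capillary-type endothelial genes rose in 6 of 19 cases, also over the list alone (camera adjusted p = 0.00646). Nid1 was up by 1.75, the adhesion molecule gene Vcam1 by 1.70 and Icam1 by 1.5. None of the 22 sinusoidal markers passed in edgeR, and 1 rose without control library 1 (camera adjusted p = 0.916 for the list in the reported fit), and the list had a median of -0.03, a mean of 0.02, a test direction of lower, and 3 genes that rose with scaling by total counts. Stab2 had a log2 change of -0.03 (adjusted p = 0.935, and 0.22 with scaling by total counts). The estimated correlation gave an adjusted p of 0.402 for the collagen, remodelling, stellate, TGF-beta and capillary lists and 0.98 for the sinusoidal list.

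Some white blood cell markers and 2 of 15 ductular markers were higher than in control livers, and the counts depended on single libraries. Monocyte and macrophage markers rose in 11 of 19 cases, or 12 over the list alone (camera adjusted p = 8.02e-06). Trem2 was up by 3.13 and Cd14 by 2.39. The number was 5 without control library 1 or sulodexide library 3, 3 without control library 2, 6 without control library 3 and 7 without sulodexide library 2. Kupffer cell markers rose in 6 of 13 cases and fell in 1, or 7 and 1 over the list alone (camera adjusted p = 0.0191). Id3 was up by 0.82. The number that rose was 2 without control library 1, control library 2, sulodexide library 2 or sulodexide library 3 and 1 without control library 3, none fell without sulodexide library 3, and the list did not pass without sulodexide library 2 (0.0845) or 3 (0.0546) or with scaling by total counts (0.0608). B and plasma cell markers rose in 5 of 9 cases, or 6 over the list alone (camera adjusted p = 0.00214). Jchain was up by 3.15 and Igkc by 3.39. The number was 3 without control library 1 or 3 and 2 without control library 2, sulodexide library 2 or sulodexide library 3. T and NK cell markers rose in 6 of 16 cases and fell in 1, Cd4, or 11 and 1 over the list alone (camera adjusted p = 0.000807), and rose in 0 without control library 1, control library 3 or sulodexide library 2 and in 2 without control library 2 or sulodexide library 3. Cd4 lost its call without any 1 library but sulodexide library 2 (0.0545 to 0.0837). Neutrophil markers rose in 2 of 8 cases, or 3 over the list alone (camera adjusted p = 0.0191), and in 0 without any 1 library but sulodexide library 3; the list did not pass without sulodexide library 2 (0.0883) or with scaling by total counts (0.173). Inflammatory genes rose in 5 of 17 cases and fell in 1, or 7 and 1 over the list alone (camera adjusted p = 0.0123, and 0.0977 with scaling by total counts). Tnfaip3 was up by 1.71 and Il18 down by 1.27. The number that rose was 2 without control library 1 or 2 or sulodexide library 1 or 2 and 3 without control library 3. Interferon-stimulated genes fell in 3 of 21 cases, also over the list alone (camera adjusted p = 0.0256). Ifit1 lay at a log2 change of -1.77. The list did not pass without control library 3 (0.0571) or sulodexide library 1 (0.138), where 1 gene fell. Ductular markers rose in 2 of 15 cases, or 1 over the list alone (camera adjusted p = 0.0461). Krt23 was up by 2.79. The number was 3 without sulodexide library 2 and 1 without any other library. The ductular list did not pass without control library 2 (0.106), control library 3 (0.06), sulodexide library 1 (0.257) or sulodexide library 3 (0.0546) or with scaling by total counts (0.219). With an estimated correlation, adjusted p = 0.358 for the monocyte and B cell lists, 0.484 for Kupffer cells and neutrophils, 0.406 for T and NK cells and inflammation, 0.59 for interferon and 0.633 for ductular markers.

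Against control, targets of p53 and NRF2 were high and several lists of hepatocyte genes low. p53 targets rose in 12 of 17 cases, or 13 over the list alone (camera adjusted p = 4.73e-11). Eda2r was up by 5.39, Ccng1 by 2.37 and Sesn2 by 1.93, and NRF2 targets rose in 17 of 21 cases, with 1 lower over the list alone (camera adjusted p = 1.27e-11). Cbr3 was up by 5.75, Gsta1 by 5.0, Gsta2 by 3.84 and Gstm3 by 3.80. Fetal or injury genes rose in 9 of 16 cases, or 11 with 1 lower over the list alone (camera adjusted p = 1.19e-06). Gpc3 was up by 6.78, Afp by 4.10, Golm1 by 2.67 and Anxa5 by 1.32. Cell cycle genes rose in 8 of 27 cases, also over the list alone (camera adjusted p = 0.00013). Ccnd1 was up by 2.05, Plk1 by 2.73 and Cdc20 by 2.29. The number was 5 without control library 1 or 2 and 4 without control library 3 or sulodexide library 3. Pericentral genes fell in 10 of 20 cases and rose in 3, also over the list alone (camera adjusted p = 0.00235). Oat lay at a log2 change of -4.18 and the glutamine synthetase gene Glul at -2.08. Periportal genes fell in 9 of 18 cases, or 11 with 1 higher over the list alone (camera adjusted p = 0.000807). G6pc lay at a log2 change of -1.91, Pigr at -1.41, Otc at -1.36 and Pck1 at -1.03. Coagulation genes fell in 16 of 21 cases, or 17 over the list alone (camera adjusted p = 1.74e-06). Klkb1 lay at a log2 change of -1.68, F7 at -0.93, Proc at -0.88, F9 at -0.73 and Serpind1 at -0.70. The number was 10 without control library 2, control library 3 or sulodexide library 1 or with scaling by total counts, where 2 rose. Bile acid genes fell in 8 of 19 cases and rose in 2, or 11 and 3 over the list alone (camera adjusted p = 0.00302). Slc10a1 lay at a log2 change of -1.37 and Cyp27a1 and Baat at -1.03, while Abcc4 rose by 4.10. With scaling by total counts 5 fell. Phase I enzymes fell in 10 of 24 cases and rose in 3, or 11 and 3 over the list alone (camera adjusted p = 0.0362, but 0.053 without control library 3, 0.0883 without sulodexide library 2 and 0.0753 with rank-based camera). Cyp2c37 lay at a log2 change of -2.94, Cyp2c29 at -2.78 and Cyp2e1 at -1.55, while Cyp2a5 rose by 2.15. Male-biased genes fell in 6 of 16 cases and rose in 1, or 10 and 1 over the list alone (camera adjusted p = 7.74e-05). Serpina12 lay at a log2 change of -2.48, C8b at -1.47 and Ugt2b1 at -1.16; none rose without control library 1 or 2 or sulodexide library 2 or 3. Female-biased genes rose in 4 of 9 cases, also over the list alone (camera adjusted p = 0.0123, and 0.0977 with scaling by total counts). Cyp2b9 was up by 3.97 and Cyp3a44 by 6.85. Mitochondrially encoded genes fell in 12 of 13 cases, also over the list alone (camera adjusted p = 1.54e-07). mt-Nd3 lay at a log2 change of -1.66 and mt-Nd2 at -1.36. With quantile normalization 6 fell. The estimated correlation gave an adjusted p of 0.134 for the p53 and NRF2 lists, 0.311 for the fetal and pericentral lists, 0.406 and 0.402 for the male-biased and female-biased lists and 0.358 for the others.

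Of the remaining lists against control, acute-phase genes (6 of 21 higher, 2 lower, camera adjusted p = 0.098) passed without control library 3 (0.017) or sulodexide library 1 (0.0465), and 2 rose without control library 2. Genes of heparan sulfate, chondroitin and hyaluronan metabolism did not pass (2 of 29 higher, 5 lower, also over the list alone, camera adjusted p = 0.952, and adjusted p = 0.98 with an estimated correlation), and their median of 0.17 and mean of 0.34 were opposite in sign to the test. Sulf2 rose by 1.17, whereas Sdc2 lay at a log2 change of -0.88 and the sulfotransferase gene Ndst2 at -0.50, and Hpse did not pass (log2 change 0.70, adjusted p = 0.0687). In that list 3 fell without control library 1, 2 or 3, 4 rose without sulodexide library 1, and 8 rose and 1 fell with scaling by total counts. The lists of fatty acid oxidation (0.295), lipogenesis (0.497), cholesterol synthesis (0.952), the unfolded protein response (0.345), the circadian clock (0.835) and red blood cells (0.952) did not pass.

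The genes that changed with sulodexide against vehicle were nearly all genes that differed the other way between TAA with vehicle and control. Of the 658 genes, 631 had been called in the opposite direction with TAA, against 147 expected if the calls were independent, and 4 in the same direction, against 139 expected. Among the 631 genes, 453 rose with TAA and were lower with sulodexide, such as Col1a1, Cd34 and Cldn7, and 178 fell and were higher, such as F9, Cd163 and Cyp7a1. The number of opposite calls was 171 without vehicle library 1, 137 without vehicle library 3, 136 without sulodexide library 2 and 345 without sulodexide library 3. Of the 5953 genes changed with TAA, 2850 were also changed with sulodexide against control, 2849 of them in the same direction, and 3103 were not. The comparisons of vehicle with control and of sulodexide with vehicle share the vehicle libraries, which by itself gives a negative relation between their log2 changes. The covariance of the log2 changes over all genes was -0.432, against a mean of -0.0467 (range -0.05 to -0.0429) in 50 simulations in which only the sharing was at work, and the correlation was -0.717 against -0.487 (-0.512 to -0.456). The signs were opposite in 76% of the genes, against 66.4% (65.5% to 67.4%) in the simulations. With no vehicle library on both sides, the covariance was -0.368, -0.374 and -0.403. The vehicle libraries cannot be split into sets of 2 or more each, so part of the excess may come from their sharing.

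**Figure D3:**
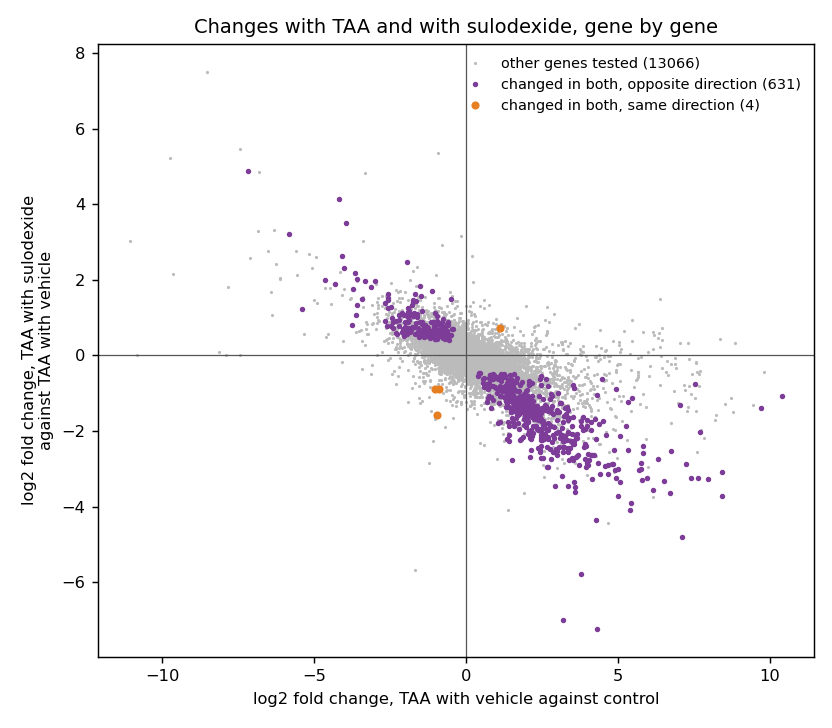
Fitted log2 fold change of each tested gene for TAA with vehicle against control (horizontal axis) and for TAA with sulodexide against TAA with vehicle (vertical axis), with 1 point per gene. The 631 genes called in opposite directions and the 4 in the same direction are coloured.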

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

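Scaling by total counts, the limma fit to FPKM and the fit without robust estimation were chosen only after the results were seen, and the other alternatives were fixed before the data were examined.

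With an absolute log2 fold change of at least 1 required, 3029 genes changed with TAA, 423 with sulodexide against vehicle and 1314 with sulodexide against control, and 405 were called in opposite directions; the fold minimum accounts for the lower counts. For sulodexide against vehicle, a fit to only the 6 libraries compared gave 386 genes and the DESeq2 Wald test gave 1142, and the causes were not tested. Leaving out 1 library gave 140 to 859 genes for sulodexide against vehicle, 2033 to 2963 against control and 136 to 824 opposite calls. With an estimated correlation, 0 lists passed camera in each comparison, against 24, 22 and 24 with the preset one. With the replicate numbers as a block, 5766, 649 and 2984 genes changed and 616 had opposite calls, and the TGF-beta list passed with sulodexide against control (camera adjusted p = 0.0378). Those numbers do not seem to pair the samples, as deviations of libraries with the same number correlated at -0.07 to 0.142 and 3 of 9 libraries matched their own number best.

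Some results that did not pass changed sign. The sinusoidal list against control had a camera adjusted p of 0.998 with scaling by total counts and of 0.811, 0.898 and 0.859 without control library 1, sulodexide library 1 and sulodexide library 3, with 0.338 the lowest value with 1 library left out (sulodexide library 2). The heparan sulfate list against control had 0.976 with the block and 0.714 and 0.849 without control library 1 and sulodexide library 3. Stab2 had log2 changes with TAA of 0.05 with scaling by total counts and 0.05 in FPKM. With sulodexide against control these were 0.22 and 0.15, and 0.09 without control library 1, 0.09 without sulodexide library 1 0.10 without sulodexide library 3 and -0.34 without sulodexide library 2. Serpinc1 with sulodexide against vehicle had -0.01 with quantile normalization.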

Other observations

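All genes named in these opening paragraphs were chosen after their values were seen. A small set of genes moved in the same direction with TAA and with sulodexide. Nr1d1 went from 25.8 CPM in control to 55.8 with vehicle and 92.0 with sulodexide. The insulin-responsive lipogenic regulator gene Srebf1 went from 246 to 133 and 72.5 CPM, the glucose-6-phosphatase gene G6pc from 1090 to 540 and 291 CPM and the imprinted RNA gene Meg3 from 12.1 to 6.29 and 2.12 CPM. The edgeR calls of G6pc and Srebf1 against vehicle were each lost without 5 of the 6 libraries left out singly.

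A further 23 genes changed with sulodexide but were not called with TAA. Saa1 had 90.3 CPM in control, 52.6 with vehicle and 397 with sulodexide, and Serpina3n had 650, 493 and 1050 CPM. Insig1 had 383, 292 and 175 CPM. Mcm10 fell with TAA, from 166 to 13.1 CPM, and stood at 59.1 CPM with sulodexide, whereas Mcm6 rose with TAA. Ccnd1 stood at 129 CPM with sulodexide, against 131 with vehicle and 31.0 in control, while other cell cycle genes such as Mki67 were lower. Clock genes of opposite phase, Arntl and Npas2 on the one side and Dbp and Per3 on the other, moved by 2.32, 5.08, -1.68 and -2.14 on the log2 scale with TAA. As the time of killing is not given in the labels, a shift in time and an effect of TAA cannot be told apart for rhythmic genes in this comparison.

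Of the tests below, those of the shared vehicle libraries and of other divisions of the libraries were written down before the result was seen, and the others were chosen only after it was seen. Changes with sulodexide ran opposite to those with TAA. Shared vehicle libraries are unlikely to account for this alone, as the covariance with no vehicle library on both sides was at weakest -0.368. A uniformly weaker TAA effect in the sulodexide mice may be another explanation, but p53 targets kept a median share of 0.97 of their TAA change (quartiles 0.75 and 1, 15 genes), against 0.33 for collagens (0.27 and 0.4, 26 genes). A response that levels off at low exposure could still give this.

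Matrix and ductular genes were lower with sulodexide. A lower share of all cells other than hepatocytes is unlikely as the cause, as the lower quartile of the log2 changes of sinusoidal markers was 0.02 and that of Kupffer cell markers 0.13, while the upper quartile was -0.67 for collagens and -1.62 for ductular markers. T and NK cell markers lay lower, however (quartiles -0.93 and -0.26, median -0.78), in a range that overlaps that of the collagens, so a lower share of some of these cells stays open. Scaling is unlikely as the cause, as a factor moves all genes of a library alike, and the upper quartile of the 44 collagen and ductular genes was -0.85, below the lower quartile of -0.23 for the other 13657 genes. Whether there may have been fewer stellate and duct cells or less expression per cell was not tested.

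Clock genes were higher with sulodexide. A different time of day at killing could give such a change, and clock genes of the opposite phase had a median log2 change of 0.10 (quartiles -0.38 and 0.21, 5 genes) against 0.73 for the others (0.33 and 0.93, 12 genes). A shift in time and an effect of treatment cannot be told apart here, as the time of killing is not given in the labels.

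The 6 libraries of each comparison can be split in only 10 ways, too few for a share under 0.05. For genes changed the number of splits with at least the real value was 1 in each comparison, with real values of 5953, 658 and 3101 and a highest other value of 1 in edgeR. For lists passing camera it was also 1 in each, but with up to 22, 20 and 18 in mixed splits against a real 24, 22 and 24. Of 100 groupings of the 9 libraries, 3 gave at least 631 opposite calls, the real one among them. Nearly all others split up the control libraries, so this does not test vehicle against sulodexide. Only 4 of the others kept the control libraries as an outer group and mixed vehicle with sulodexide libraries, with 0 opposite calls at most, too few for a share under 0.05 of such divisions. The 2 others, with 2517 and 2636 calls, kept the control libraries as the shared group, and the highest number among the rest was 1.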
